A study of Mus musculus with 15 samples.

How the data were processed

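RNA was measured by bulk RNA sequencing in 15 libraries from mice of strain 129, which the labels describe as 10-week-old males and number at 10 animals. Sex-linked genes, given at the end, go against the label of male in most of these libraries. Of these, 6 came from muscle stem cells (MuSCs), the satellite cells that repair skeletal muscle, obtained by biopsy. Among the MuSC libraries, 3 were taken before autologous MuSC transplantation and 3 after it, from an area that had not received cells. The other 9 libraries came from quadriceps femoris muscle, 6 from transplanted mice and 3 from sham-operated mice. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. Libraries are named here by group and mouse number, such as after 5 or sham 12.

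The authors deposited 3 tables, 1 of the MuSC libraries and 2 of muscle. The first muscle table holds 3 transplanted libraries (4, 14 and 94) and 2 shams (3 and 192), and the other holds 3 transplanted libraries (5, 6 and 11) and 1 sham (12). They are called the 2-sham table and the 1-sham table below. Each of the deposited tables gives estimated counts, TPM and FPKM for 56953 genes, per the file headers. The deposited estimated counts were not all whole numbers and were rounded before testing. TPM and FPKM in the authors' tables are values scaled for gene length and library total, with no further scaling between libraries seen in them. The aligner, the quantifier and the annotation release are not given in the sources used here. The submitters' processing notes list GRCm38 and mm10, but of the 52029 genes shared with the GENCODE annotation of GRCm38 used here only 1446 had the same coordinates, so no coordinates are printed. That annotation was used for gene length and type alone, matched by gene identifier. Another 3 columns held values of a library that matched no sample's labels, and they were not used.

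Groups were taken from the labels. The treatment entry of the sham libraries names transplantation, so sham and transplanted muscle were told apart by their titles. The mouse numbers are 5, 6 and 11 in both MuSC groups, and the labels describe the cells after transplantation as autologous, so the numbers were taken to pair the libraries. The deviations from the group means correlated across genes at 0.30 for mouse 5, 0.36 for mouse 6 and -0.40 for mouse 11. Between different mice they correlated at 0.55 for after 11 with before 6 and 0.49 for after 5 with before 11. These values exceed those of the same mouse, and the other different-mouse values were -0.68 to -0.16. Every positive value joined libraries of the same library set (A or B, described below). The pairing thus rests on the labels and is not borne out by these correlations. No pair of libraries in 1 group and table agreed within sampling noise (chi-square per degree of freedom 18.26 to 506.17), so none was treated as a duplicate.

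Total estimated counts ranged from 17.09 to 22.98 M per library (M for mega), with 17873 to 20284 genes detected. Counting intervals and floors cover counting error only. Where all libraries of a group had a count of 0, the fold was bounded against a floor of 3 counts over the group and written as at least that fold.

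The MuSC table was tested as 3 libraries after against 3 before with no covariate. Muscle was tested as 6 transplanted against 3 sham libraries with the table as a term, so that only differences within a table entered. Both used edgeR's quasi-likelihood test on the rounded counts, with filterByExpr (minimum count 10), TMM scaling and Benjamini-Hochberg adjustment, 2-sided, with a threshold of 0.05 on the adjusted p. CPM values are counts scaled to a common total by the library's TMM-scaled size. The standard error of a log2 fold change was taken as its size over the root of the F statistic. Gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. The 37 lists cover stem cell identity and state, metabolism, stress and signalling, fibre types and markers of other cell types, and a list needed at least 3 measured genes to be tested. The ribosomal protein list also holds the elongation factor Eef1a1. The design, the lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined.

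Named genes were to be the 10 with the largest positive and the 10 with the largest negative fold change among those past the threshold in the same direction throughout. Fewer than 10 genes passed in each comparison, so the rule named the 5 highest and 5 lowest by signed F statistic as genes that do not pass, leaving out predicted genes and pseudogenes. It also named 10 genes per comparison whatever their values, and 2 members of every list past the threshold. The fold changes of both comparisons were correlated across genes, and that value was set beside fits to relabelled libraries.

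Alternatives were DESeq2, its size factors, other filters, limma on log2(FPKM + 0.1) and on log2(FPKM + 1) scaled by the median of log ratios, each library left out in turn, the mouse as a block, and each muscle table alone. Further ones were chosen after seeing the data: limma on log2(FPKM + 1) without that scaling, offsets corrected for each library's trend with transcript length (a spline with 5 degrees of freedom), and the omission of pairs of libraries. The MuSC libraries were also divided by the ratio of their FPKM sum to their TPM sum, which lay under 0.9 in after 5, before 5 and before 11 (set A) and over it in after 6, after 11 and before 6 (set B). The sets differed in the trend of log2 TPM with log2 transcript length, at slopes of 0.15 to 0.245 in set A and -0.314 to -0.147 in set B.

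The test was checked on simulated counts with known changes. With the spread of the MuSC libraries (13196 genes in the step), 0% of 100 genes changed by a log2 fold of 1 and 2% of 100 changed by 2 were recovered, with 0 false calls. With the spread of the muscle libraries (14111 genes), 75% and 98% were recovered, with 12 false calls. With no simulated change, 0 genes passed in either comparison, and 1 list passed with the MuSC spread and 0 with the muscle spread. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.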

Results

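The study sampled MuSCs and quadriceps muscle of mice that received their own MuSCs back, or a sham operation. MuSC libraries came from mice 5, 6 and 11 before transplantation and from the same mice after it, 3 in each group. Total estimated counts were 21.26 M in before 5, 17.09 M in before 6 and 18.67 M in before 11. They were 18.12 M in after 5, 20.96 M in after 6 and 19.26 M in after 11. In muscle, the 6 transplanted libraries held 22.51 M (mouse 4), 21.9 M (14), 18.07 M (94), 22.29 M (5), 22.35 M (6) and 22.98 M (11). The 3 shams held 18.11 M (mouse 3), 18.38 M (192) and 18.83 M (12). The titles number the mice, so libraries of a group were taken to come from separate animals, and the muscle p-values below measure the spread between animals. The main MuSC test left the libraries of each mouse unpaired. Its spread within groups also holds the difference between library sets A and B, so its p-values do not measure the spread between animals alone.

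The first comparison asked how endogenous MuSCs outside the transplanted area differed after transplantation from those before it. The 5 genes that stood highest relative to their error were, in this order, Hoxc12, Hoxc13, Sorcs2, Hoxc11 and Bmp7, of which Hoxc11, Hoxc12 and Hoxc13 are homeobox genes at the 5′ end of the HoxC cluster that mark posterior and distal position along the body and limb. No fixed list covers Hox genes, so they were not tested as a group. Hoxc13 (ENSMUSG00000001655.7) averaged 8.63 ± 2.46 CPM after (SD, n = 3) and 0.949 ± 0.339 CPM before (n = 3), a log2 difference of 3.18 ± 0.48 (SE). Hoxc11 (ENSMUSG00000001656.4) averaged 33.2 ± 10.1 CPM after and 9.31 ± 2.44 CPM before, a difference of 1.83 ± 0.36. Hoxc12 (ENSMUSG00000050328.3) had 44 counts over the 3 libraries after and 0 before, at least 15.7-fold higher. Six2, a homeobox transcription factor of mesenchymal progenitors, stood near the lower end of the ranking, at 0.593 ± 0.593 CPM after and 12.04 ± 4.02 CPM before (-4.34 ± 0.90).

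Hoxc11, Hoxc12, Hoxc13 and Six2 each differed in the same direction in 3 of 3 mice, with no overlap between the groups, and so did the other genes that the rule placed at either end. The rule picked these genes as extremes, so this says little beyond their rank. Of all 13512 genes tested, 2849 went the same way in 3 of 3 mice. Bmp7, a secreted morphogen, averaged 48.2 ± 65.7 CPM after and 0.536 ± 0.387 CPM before. Its value of 124 CPM in after 5 set that mean, against 15.3 CPM in after 6 and 5.49 CPM in after 11. Sorcs2, a sorting receptor, averaged 46.9 ± 9.97 CPM after and 15.6 ± 1.81 CPM before. At the lower end, Adam23 had 0 counts after and 42 before, at least 13.1-fold lower. Lvrn averaged 1.09 ± 0.0706 CPM after and 5.63 ± 3.14 CPM before. Cavin2, a coat protein of caveolae, averaged 3.84 ± 1.45 CPM after and 21.4 ± 14.0 CPM before, and Plin4, a lipid droplet protein, 0.501 ± 0.250 and 2.86 ± 0.856 CPM. Whether reads were counted by strand is not given in the sources used here, so counts of HoxC genes are uncertain where antisense transcripts such as Hotair overlap them.

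**Figure D1:**
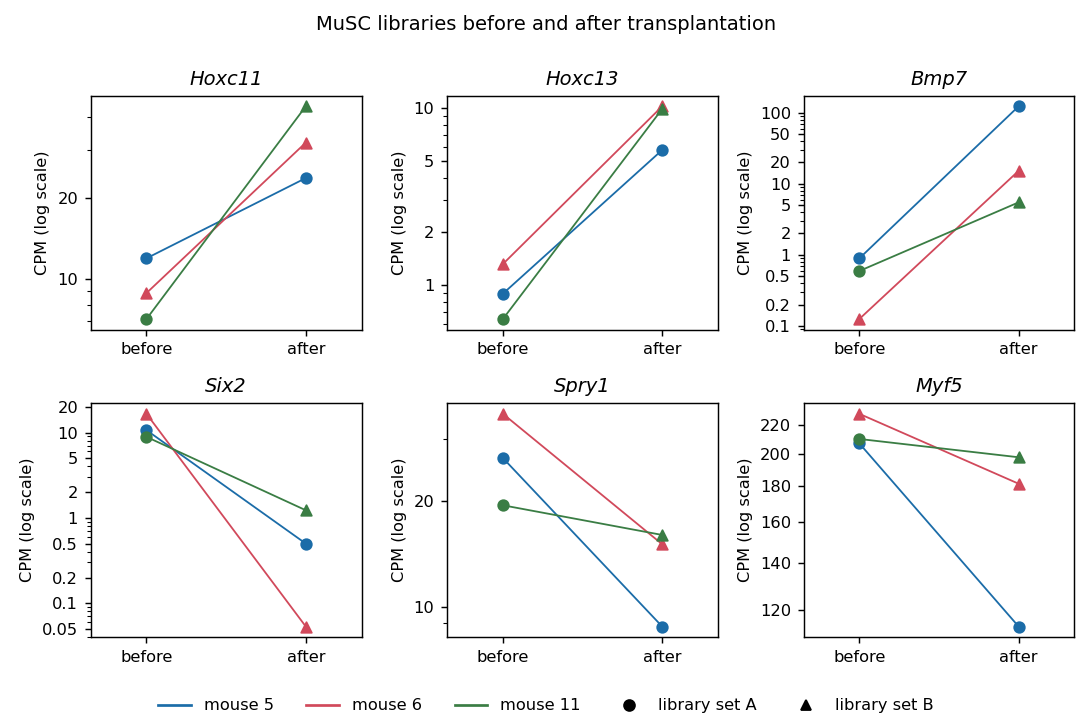
CPM on a log scale for 6 genes in the MuSC libraries before and after transplantation, with lines joining libraries of the same mouse and symbols giving the library set (circles, set A; triangles, set B). Hoxc11 and Hoxc13 lie higher and Six2 lower after transplantation in 3 of 3 mice, and Bmp7 ranges from 5.49 to 124 CPM after. These genes were picked as extremes of the ranking.

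None of these differences passed. Of 13512 genes tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05 (smallest adjusted p = 0.873), with 305 at an unadjusted p under 0.05, while DESeq2 called 16, of which 13 were higher after. DESeq2's calls included Hoxc11, Hoxc12, Hoxc13, Bmp7, Sorcs2, Six2, Lvrn and Cavin2, with an adjusted p of 1.31e-06 for Hoxc13, 7.4e-06 for Bmp7, 0.000163 for Six2, 0.00121 for Sorcs2, 0.00769 for Hoxc11, 0.0309 for Lvrn and Cavin2 and 0.048 for Hoxc12. For each of these genes that value was the lowest over its alternatives and the highest was 1. The groups did not overlap in 855 genes (6.3%), where chance gives 10%. With the mouse as a block, edgeR also called 0 genes (214 at an unadjusted p under 0.05). Within set A alone, with 1 library after and 2 before, 43 genes passed, and within set B alone, with 2 after and 1 before, 0 did, with the lone library of each set assumed to vary like the others, here and for the list medians within sets. Without after 5 the unadjusted count was 3545, without before 5 it was 159 and without before 11 it was 151, each with 0 genes past the threshold. Omitting after 5 leaves only libraries of set B after, so that count also holds the difference between the sets. Without both after 5 and after 11, which leaves after 6 as the lone library after, assumed to vary like those before, 4 genes passed (Igfbp4, Esx1, Laptm5 and Cxcl3, named after their values were seen).

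None of the genes followed for MuSC identity and activation passed. Pax7, the transcription factor that marks MuSCs, averaged 74.8 ± 29.6 CPM after and 71.0 ± 7.60 CPM before (log2 difference 0.07 ± 0.36). Myf5 averaged 164 ± 44.6 and 215 ± 11.4 CPM (-0.39 ± 0.29) and was lower after in 3 of 3 mice with no overlap. Myod1 averaged 1311 ± 604 and 1047 ± 383 CPM (0.32 ± 0.49), and Myog, which marks differentiation, 126 ± 62.8 and 175 ± 110 CPM (-0.48 ± 0.66). Spry1, a receptor tyrosine kinase inhibitor needed for return to quiescence, was at 13.3 ± 3.93 and 27.1 ± 8.00 CPM (-1.03 ± 0.37, adjusted p = 0.873) and lower after in 3 of 3 mice with no overlap. Vcam1 differed by -0.06 ± 0.38, Cdkn1a by -0.12 ± 0.45 and Fos by -0.32 ± 0.43. Mki67, a proliferation marker, ranged from 8.47 CPM in after 11 to 193.3 CPM in after 5 (0.12 ± 0.97). Cd34 had 17 counts after and 34 before over 3 libraries each and was too low to test.

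Of 30 gene lists tested in MuSCs, 5 passed with camera's preset correlation, 4 toward higher and 1 toward lower expression after transplantation. With an estimated correlation 0 of the 5 passed (adjusted p = 0.843 for each with an estimated correlation), and 0 passed with fry (adjusted p = 0.868 for each). In the inflammatory cytokine list, 9 of 9 measured members were positive (median 0.89, adjusted p = 0.00187) and the list's mean was higher in 3 of 3 mice. Of its genes 0 passed over all genes tested, and 2 passed when adjusted over the list alone. Cxcl1, a neutrophil chemoattractant, was at 5.19, 1.22 and 106 CPM in after 5, 6 and 11 and at most 0.875 CPM before, and Cxcl5 at 19.0, 0.905 and 1.64 CPM after and at most 0.340 CPM before. In the cell cycle list, 17 of 20 members were positive (median 0.45, adjusted p = 0.00187), among them the replication licensing gene Mcm2 (0.85 ± 0.37) and E2f1 (0.88 ± 0.54), and its mean was higher in 3 of 3 mice. In the list of mature myofibre markers, 10 of 10 members were negative (median -0.76, adjusted p = 0.00187), with Tcap at -1.67 ± 0.70 and Myh4 at -1.33 ± 1.03, but the list's mean was lower in 2 of 3 mice. Glycolysis genes were positive in 14 of 17 (median 0.41, adjusted p = 0.0229; Pfkl 0.80 ± 0.39, Gapdh 0.75 ± 0.47), and ribosomal protein genes in 17 of 20 (median 0.59, adjusted p = 0.0484; Rpl32 1.05 ± 0.65, Rplp1 0.94 ± 0.78), and both list means were higher in 2 of 3 mice. The cell cycle, mature myofibre, glycolysis and ribosomal protein lists had 0 genes past the threshold, over all genes or adjusted over the list alone. Gapdh, Rpl32 and Rplp1 have many processed pseudogenes, so their counts are uncertain.

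After 11 had 1.2% mitochondrial counts (4.4 to 6.3% in the other MuSC libraries), the fewest genes detected (17873) and the steepest slope with transcript length (-0.314). In after 11 the mature myofibre list stood at -2.93 (mean centred log2 CPM, against -0.29 to 1.05 in the other libraries) and the interferon list at 3.01 (against -0.83 to -0.30), and in after 5 the fibroadipogenic markers stood at 1.33 (against -1.45 to 0.30). With the mouse as a block 9 lists passed: these 5, with mature myofibre markers at -1.50, and those of MuSC quiescence, fast fibres, slow fibres and fibroadipogenic markers (adjusted p 0.0397, 0.00162, 0.000765 and 0.0103), and the estimated correlation gave adjusted p = 0.736 for each. Over 22 alternatives the adjusted p ran from 2.07e-08 to 0.868 for cytokines, 4.14e-05 to 0.868 for cell cycle, 4.6e-10 to 0.868 for mature myofibre markers, 0.00309 to 0.868 for glycolysis and 0.000136 to 0.898 for ribosomal proteins. The inflammatory call was lost without after 5 (0.97) and without both after 5 and after 11 (0.20), and its median was 1.34 without before 5. The mature myofibre call was lost without after 11 (-0.22), the median was -1.31 and past the threshold with after 6 as the lone library after, and its median was -2.13 without after 5 and -0.47 without before 5. The glycolysis call was lost without after 6, after 11, before 5 or before 11 (0.37, 0.17, 0.33 and 0.31), and so was the ribosomal protein call (0.53, 0.23, 0.45 and 0.41), whose median was 0.94 without after 5 and 0.97 without before 6. Without after 5 the libraries after were all of set B, and without before 6 those before were all of set A. Values from these omissions thus also hold the difference between the sets.

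The ribosomal protein median was -0.24 in set A alone, which holds 1 library after, and past the threshold, 0.44 in set B alone, which holds 1 library before, also past it, 0.02 with the set as a term and 0.28 with length-corrected offsets. For glycolysis these values were -0.04, 0.36, 0.18 and 0.37, none past the threshold, while it was 0.29 and past it with the mouse block and length-corrected offsets. The mature myofibre median was 0.38 in set A and -1.95 in set B, the inflammatory median was 2.41 in set B, and the cell cycle median fell short of the threshold in set A (0.13). With the set as a term 12 lists passed, with set A alone 12 and with set B alone 9.

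The other 25 lists did not pass in the MuSC test (adjusted p 0.0517 to 0.983). Among markers of other cells, 3 of 4 measured fibroadipogenic genes were positive (median 1.44, adjusted p = 0.0688) and so were 3 of 4 endothelial genes (median 0.29, adjusted p = 0.357). Members of the MuSC quiescence list were negative in 9 of 14 (median -0.13, adjusted p = 0.0517), of the fast fibre list in 11 of 12 (-0.33, adjusted p = 0.0517) and of the slow fibre list in 10 of 11 (-0.36, adjusted p = 0.123). The MuSC identity list had 8 positive and 6 negative members (median 0.03, mean -0.07). Median, mean and test differed in sign for that list and for those of extracellular matrix, atrophy and autophagy, and the circadian clock. Another 7 lists, among them adipocyte, macrophage and tenocyte markers, had too few measured genes.

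The other comparison asked how hindlimb muscle differed between transplanted and sham-operated mice. Ddit4 (ENSMUSG00000020108.5), a stress-induced inhibitor of mTORC1, averaged 9.85 ± 3.26 CPM in transplanted muscle (SD, n = 6) and 2.89 ± 0.550 CPM in shams (n = 3), a log2 difference of 1.77 ± 0.29 (SE). Immediate early genes stood at the lower end: Ier2 (ENSMUSG00000053560.6) averaged 4.65 ± 0.941 CPM against 10.2 ± 2.80 CPM (-1.20 ± 0.19), and Egr1 (ENSMUSG00000038418.8) 11.2 ± 6.17 CPM against 53.1 ± 15.7 CPM (-2.33 ± 0.42). For these 3 genes, picked as extremes of the ranking, the transplanted and sham libraries did not overlap. Also at the lower end were Acvr1c, an activin receptor, at 0.729 ± 0.473 against 3.37 ± 2.14 CPM (-2.28 ± 0.48), Sncg at 5.81 ± 4.11 against 16.6 ± 16.2 CPM (-1.62 ± 0.34), and Fads1, a fatty acid desaturase, at 7.43 ± 1.14 against 14.6 ± 7.78 CPM (-1.0 ± 0.20). At the upper end, Med26, Fhl3, Rpp25l and the NF-κB inhibitor Nfkbia differed by 0.61 ± 0.12, 0.51 ± 0.11, 0.49 ± 0.11 and 0.46 ± 0.11.

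**Figure D2:**
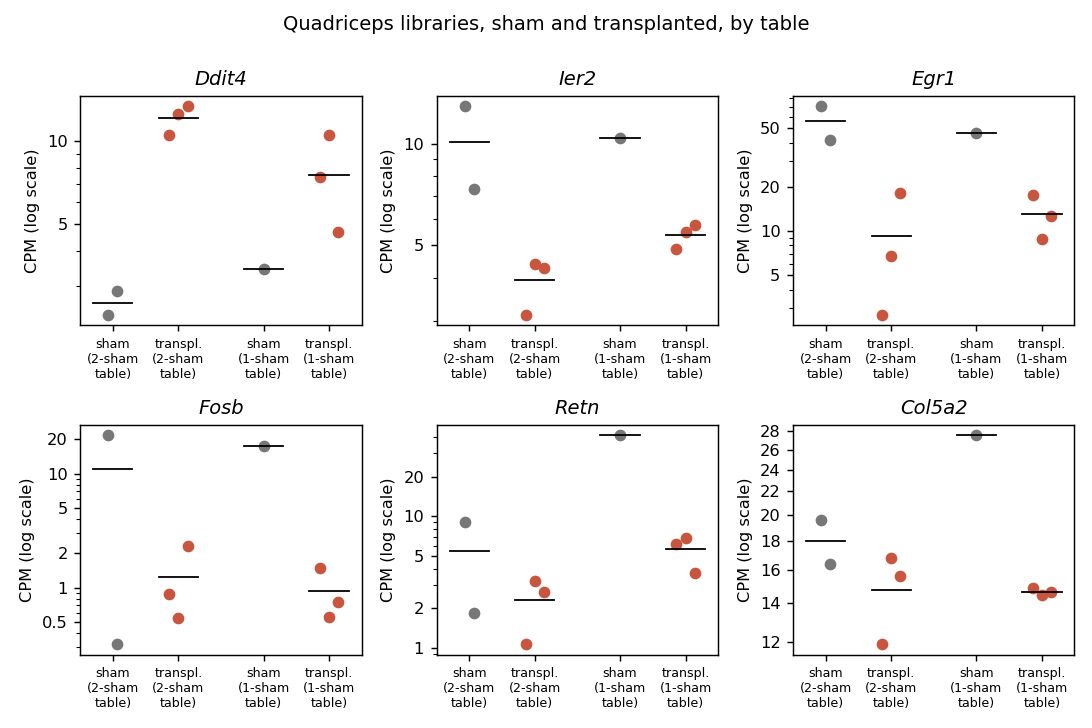
CPM on a log scale for 6 genes in the quadriceps libraries, with 1 point per library (grey, sham; red, transplanted), bars at the means and the 2 deposited tables side by side. Ddit4 lies at 4.71 to 13.4 CPM in transplanted muscle and 2.36 to 3.46 CPM in shams, while Fosb in sham 192 (0.318 CPM) lies below the transplanted libraries.

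Of 14375 genes tested, edgeR called 0 (smallest adjusted p = 0.423), with 1018 at an unadjusted p under 0.05. DESeq2 called 6, among them Ddit4, Ier2, Fads1 and Acvr1c, and with no filter on low counts edgeR called 12. These 12 included Ddit4 and Egr1 (adjusted p = 0.00337 for each), Ier2 (0.0139), Fosb (0.0142), Sncg (0.0193), Retn (0.0241), Fads1 (0.0259) and Acvr1c (0.0275). Over the alternatives of these genes the adjusted p ran from 5.81e-06 to 0.91 for Ddit4, and up to 1 for the others. Transplanted and sham libraries did not overlap in 303 genes (2.1%), where chance gives 2.4%. In the 2-sham table alone 1 gene passed, Ddit4 (2.21, adjusted p = 0.048, with 5.81e-06 to 0.91 over its alternatives), and in the 1-sham table alone 41 did, 19 higher and 22 lower in transplanted muscle, with the lone sham assumed to vary like the transplanted libraries. Without transplanted 94, 2 genes passed (Lars2 and the ribosomal RNA-like Rn18s-rs5, whose reads are hard to assign), and without sham 192, 4 passed (Fosb, Retn, Fos and Acaca), all named after their values were seen. Without sham 12, which takes the 1-sham table out of the contrast, the unadjusted count was 499.

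Myosin heavy chains and the other genes followed in muscle did not pass. The adult fast isoform Myh4 averaged 49560 ± 10570 CPM in transplanted and 50110 ± 5462 CPM in sham muscle (0.02 ± 0.16), Myh1 6528 ± 1519 and 5265 ± 2823 CPM (0.32 ± 0.33), Myh2 2575 ± 889 and 2021 ± 1058 CPM (0.32 ± 0.42), and the slow isoform Myh7 695 ± 436 and 575 ± 378 CPM (0.05 ± 0.71). Embryonic Myh3, which marks regenerating fibres, was at 4.63 ± 3.21 and 4.06 ± 1.45 CPM (-0.03 ± 0.52). Pax7 differed by -0.46 ± 0.39, Myod1 by -0.13 ± 0.11, Col1a1 by -0.42 ± 0.23, the atrophy ligase Fbxo32 by -0.07 ± 0.22 and Cdkn1a by 0.34 ± 0.21. In the 1-sham table alone Myh2 passed (1.82, adjusted p = 0.0483, with 0.0483 to 1 over its alternatives).

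Of 35 lists tested in muscle, 12 passed with the preset correlation, 8 lower and 4 higher in transplanted muscle. With an estimated correlation 0 of the 12 passed (adjusted p = 0.638 for each with an estimated correlation), and 0 passed with fry (adjusted p 0.534 to 0.605). Adipocyte markers were negative in 8 of 8 (median -1.43, adjusted p = 1.26e-06), and 7 passed when adjusted over the list alone, against 0 over all genes. Retn averaged 3.97 ± 2.20 against 17.4 ± 20.9 CPM (-2.04 ± 0.45), with 41.1 CPM in sham 12, 9.11 in sham 3 and 1.86 in sham 192, and Cidea differed by -2.05 ± 0.77. Extracellular matrix genes were negative in 16 of 16 (median -0.37, adjusted p = 4.4e-07; 1 adjusted over the list alone), with Col5a2 at -0.54 ± 0.14 and Col3a1 at -0.53 ± 0.18. Other markers of connective tissue moved with them: fibroadipogenic markers were negative in 11 of 13 (median -0.27, adjusted p = 0.000634; 3 adjusted over the list alone; Dpp4 -0.98 ± 0.26, Dpt -0.69 ± 0.22) and tenocyte markers in 7 of 8 (median -0.51, adjusted p = 0.00131; Kera -1.13 ± 0.42, Comp -0.84 ± 0.38). Immediate early and stress genes were negative in 12 of 19 (median -0.23, adjusted p = 0.000634; 5 adjusted over the list alone), with Fosb at -3.61 ± 0.77 beside Egr1. Antigen presentation genes were negative in 14 of 15 (median -0.30, adjusted p = 0.000119; Nlrc5 -0.96 ± 0.42, Psmb9 -0.61 ± 0.41), Wnt pathway genes in 11 of 12 (median -0.18, adjusted p = 0.0361; Tcf7l2 -0.55 ± 0.20, Sfrp1 -0.46 ± 0.33), and erythroid markers in 5 of 5 (median -0.37, adjusted p = 0.0413; Alas2 -0.66 ± 0.42, Hba-a2 -0.40 ± 0.21).

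Oxidative phosphorylation genes were positive in 19 of 19 (median 0.22, adjusted p = 1.28e-05), with Cox5b at 0.31 ± 0.16 and Cox4i1 at 0.29 ± 0.16. The median was -0.07 without sham 12, in which mitochondrial genes took 9.3% of counts, against 12.2 to 16.0% in the other muscle libraries. Members of the ribosomal protein list were positive in 18 of 20 (median 0.12, adjusted p = 0.00155), with Rpl32 at 0.21 ± 0.10 and the elongation factor Eef1a1 at -0.22 ± 0.11. Genes of atrophy and autophagy were positive in 11 of 15 (median 0.11, adjusted p = 0.0261), with Fbxo31 at 0.27 ± 0.11 and Foxo1 at 0.23 ± 0.14. Glycolysis genes were positive in 14 of 18 (median 0.15, adjusted p = 0.0261; Gapdh 0.32 ± 0.15, Pfkp -0.32 ± 0.25), where Aldoa is listed under 2 identifiers. With length-corrected offsets the ribosomal protein (0.08) and Wnt (-0.13) calls were lost. Counts of Hba-a2, Gapdh, Rpl32 and Eef1a1 are uncertain because they have near-identical copies or many pseudogenes.

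Over 23 alternatives the adjusted p ran from 3.66e-18 to 0.638 for oxidative phosphorylation, 6.9e-11 to 0.638 for adipocyte markers and 3.66e-10 to 0.767 for extracellular matrix, and 20 of the 23 alternatives kept the call for the last pair of lists but 9 for the Wnt and erythroid lists. Mean centred log2 CPM of the adipocyte markers was 2.21 in sham 12, 1.13 in sham 3 and -0.88 in sham 192, and 1.14 in transplanted 6 but -1.84 to -0.13 in the other transplanted libraries. Transplanted 4 and sham 12 held the lowest and highest of these means, and without both of them 0 of the 12 lists were past the threshold (adipocyte -0.70, extracellular matrix -0.03, oxidative phosphorylation -0.06). In the 2-sham and 1-sham tables alone the medians were -1.0 and -2.03 for adipocyte markers, -0.20 and -0.62 for extracellular matrix, and -0.17 and -0.33 for immediate early genes, each past the threshold. They were -0.07 and 0.73 for oxidative phosphorylation, -0.10 and -0.72 for antigen presentation and -0.07 and -0.52 for fibroadipogenic markers, with only the 1-sham value past it. For tenocyte (-0.54 and -0.41) and erythroid markers (-0.37 and -0.19) only the 2-sham value passed. For ribosomal proteins (0.05 and 0.20) and glycolysis (0.07 and 0.30) the 1-sham value passed, and for Wnt (-0.09 and -0.31) and atrophy genes (0.04 and 0.20) neither did. Without sham 12 alone the calls for oxidative phosphorylation (-0.07), antigen presentation (-0.09), fibroadipogenic markers (-0.06), ribosomal proteins (0.06), glycolysis (0.07), atrophy (0.05) and Wnt (-0.09) were lost, and the extracellular matrix median was -0.19. The 1-sham table has no other sham, so this omission takes that whole table out of the contrast. These values and those of the 2-sham table alone thus rest on the same contrast and are not separate evidence. Without sham 3 the immediate early (0.09) and erythroid (-0.06) calls were lost, and the medians were 0.41 for oxidative phosphorylation, -0.46 for antigen presentation, -0.29 for tenocyte markers and 0.23 for glycolysis. Without sham 192 the glycolysis (0.17) and Wnt (-0.21) calls were lost and the immediate early median was -0.42.

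Among the transplanted libraries, leaving out mouse 4 ended the calls for ribosomal proteins (0.08), Wnt (-0.20) and erythroid markers (-0.16), and the medians were -0.46 for antigen presentation, -0.17 for fibroadipogenic and -0.32 for tenocyte markers. Without mouse 6 the atrophy (0.06), Wnt (-0.20) and erythroid (-0.37) calls were lost, without mouse 14 (0.17) or mouse 5 (0.12) the glycolysis call, without mouse 94 the atrophy call (0.10) and without mouse 11 the erythroid call (-0.39). The other 23 muscle lists did not pass (adjusted p 0.0588 to 0.922), among them fast fibre genes, positive in 14 of 14 (median 0.14, adjusted p = 0.0588), macrophage markers, negative in 13 of 13 (median -0.17, adjusted p = 0.133), and endothelial markers (6 of 11 positive, median 0.03, adjusted p = 0.868). The macrophage markers had a mean centred log2 CPM of 0.68 in sham 12, -0.21 in sham 3 and -0.18 in sham 192. Without sham 12 they passed as higher in transplanted muscle, and slow fibre genes as lower. Median, mean and test differed in sign for endothelial markers and for the lists of fatty acid oxidation, inflammatory cytokines, the unfolded protein response, the circadian clock and p53. Neutrophil and T and NK cell markers had too few measured genes.

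The fold changes in MuSCs and in muscle were compared across the 12202 genes tested in both, to ask whether the cells and the tissue changed alike. Pearson's r across genes was 0.068 and Spearman's rho 0.181, and genes are not independent replicates. Of 839 relabellings of the libraries, 421 (50.2%) gave an r as large in size and 227 (27.1%) a rho as large, so the values lay within what other groupings gave. The relabellings took every split, including those that group both MuSC libraries of a mouse or change the number of shams by table. With the 2-sham table alone r was -0.006 and with the 1-sham table alone 0.087. With the muscle of mice 5, 6 and 11 left out, so that no mouse number stood in both comparisons, r was -0.003.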

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

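Apart from the comparison with other splits of the libraries, which was planned, the tests of explanations given here were chosen only after the result was seen, and their criteria were set with the values in view.

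Of 49 values tested in the 6 transplanted muscle libraries, 4 had a single library further from the others than Dixon's critical value for 6 allows, which chance gives for about 1 in 20. Cdkn1a stood at 63.22 CPM in transplanted 6 and at 25.0 to 34.98 CPM in the others. Fbxo31 stood at 169.5 CPM in transplanted 6 and at 138.5 to 144.8 CPM in the others. Alas2 stood at 0.3258 CPM in transplanted 4 and at 1.116 to 1.738 CPM in the others. Transplanted 94 held 18.07 M estimated counts and the others 21.9 to 22.98 M. The 3 shams held 18.11 to 18.83 M, so total counts went with the group except in transplanted 94.

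The 5′ HoxC genes stood higher and Six2 lower in MuSCs after transplantation, without passing edgeR's test over all genes. Transcript-length bias between the library sets is argued against as the whole cause for Hoxc11, Hoxc13 and Six2, because with the mouse block and length-corrected offsets the log2 differences were 1.68 ± 0.36, 3.11 ± 0.48 and -4.74 ± 0.96, against 1.83, 3.18 and -4.34 without them. The correction removes a trend with transcript length alone, so it does not bear on other differences between the sets. A second biopsy taken from another muscle or another place along the limb could give the pattern, since HoxC genes mark position, but the median of Hoxc4 to Hoxc10 (-0.13) covers members that go both ways and decides nothing: Hoxc8 (-1.29 ± 0.61) and Hoxc6 (-0.56 ± 0.29) were lower after in 3 of 3 mice without overlap. The biopsy site cannot be told apart from transplantation, because every library after transplantation came from a later biopsy of a non-transplanted area and the sites are not given in the sources used here. An effect of transplantation stays open and was not tested apart from time and the first biopsy.

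The fat, matrix and oxidative phosphorylation lists passed between transplanted and sham muscle with the preset correlation alone (adjusted p = 0.638 for each with an estimated correlation), and oxidative phosphorylation was at -0.07 in the 2-sham table. Without transplanted 4 and sham 12, 0 of the 12 list calls remained, whereas leaving out any other of the 18 pairs of 1 transplanted and 1 sham library kept 5 to 10 (median 9), and the other pairs with sham 12 kept 5 to 6. This pair was picked as the extremes of the adipocyte and matrix lists, so its omission had to shrink these differences. It leaves 2 transplanted against 2 sham libraries in the only table with a contrast. Leaving out transplanted 14 or 94 with sham 12 gave the same sizes and kept 6 calls each. Transplanted 5, 6 or 11 with sham 12 left the same contrast as omitting sham 12 alone. Because the pair was picked as extremes, the comparison does not decide whether the tissue makeup of these libraries, such as fat or tendon taken along, could account for the calls. A lower share of muscle fibres in the shams would raise the markers of all other cell types alike. The mean log2 differences of endothelial (-0.01) and adipocyte markers lay 4.97 SD apart, over genes and not animals. These lists were picked with their values in view, and adipocyte markers had the largest median of all lists tested, so a wide gap was fixed in advance. By library, the adipocyte mean of sham 192 (-0.88) lay within the range of transplanted muscle (-1.84 to 1.14). The gap therefore does not decide whether a lower share of fibres was the whole cause or a part of it, and both stay open. Macrophage (13 of 13) and Schwann markers (6 of 7) were also negative, and mature myofibre (8 of 10), fast (14 of 14) and slow fibre genes (11 of 11) positive. Against this, pericyte and smooth muscle markers had a median of -0.01, and B and plasma cell markers were positive in 3 of 3. Nor did these signs hold in each table. Without sham 12, which leaves the contrast of the 2-sham table, macrophage markers passed as higher and slow fibre genes as lower in transplanted muscle. An effect of transplantation on fat and connective tissue stays open.

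In MuSCs, where list calls held with the preset correlation alone (adjusted p = 0.843 for each with an estimated correlation), the ribosomal protein median of 0.59 was 0.28 with length-corrected offsets and 0.23 with the mouse block added, neither past the threshold. With the library set as a term it was 0.02, also not past it. Transcript-length bias between the sets may thus account for part of it, and differences of any kind between the sets for nearly all of it. Both stay open. For glycolysis, with a median of 0.41, the value of 0.29 with the block and length-corrected offsets, past the threshold, argues against transcript-length bias as the whole cause. But 0.37 with length-corrected offsets alone was not past it, nor was 0.18 with the set as a term, so this bias stays open. For cell cycle genes this bias is argued against as the whole cause of the call with the preset correlation, because the median of 0.45 was 0.34 with length-corrected offsets and 0.34 with the block added. Both were past the threshold, but other splits of the libraries also put lists past it, as given below. The median was 0.13 in set A alone, with 1 library after, and 0.51 in set B alone, with 1 library before. The mature myofibre median of -0.76 was -0.22 and not past the threshold without after 11, but after 11 was the lowest library of this list, so that its omission had to shrink the difference, and whether the call rests on it stays open. After 11 stood apart in 1.2% mitochondrial counts (4.4 to 6.3% in the others), the fewest genes (17873) and the highest interferon list mean, so library quality and a biological difference both stay open and were not tested.

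Other splits of the libraries bear on the counts themselves. For genes, the real count of 0 is reached by every split by construction (10 of 10 in MuSCs and 84 of 84 in muscle), so this says nothing about chance. The highest other count of MuSC genes was 4366, for the split that follows library sets A and B, which points to a structure of the libraries. For MuSC lists, 8 of 10 splits gave at least the 5 lists of the real one, with 15 as the highest other, and among the 4 splits that part every pair of the same mouse the highest other was 12. With 10 splits no share under 0.05 can be reached. In muscle, the highest other count was 37 genes, and 25 of 84 splits gave at least 12 lists (highest other 22), so chance is not excluded for the number of lists. Of the 40 splits that keep 2 and 1 libraries as shams by table, 12 gave as many lists, with 16 as the highest.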

How the results depend on the processing

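The settings chosen only after the data were seen were log2(FPKM + 1), length-corrected offsets, the library sets and the omission of pairs of libraries. Where a value below moved, the cause was not tested, except that leaving out libraries or testing 1 table or set leaves fewer samples. Leaving out a MuSC library also changes how sets A and B are spread over the groups. In MuSCs, the count of 0 genes became 16 with DESeq2, 43 in set A and 4 without both after 5 and after 11, and stayed at 0 without each library in turn (151 to 3545 genes at an unadjusted p under 0.05). The count of 5 MuSC lists became 8 with log2(FPKM + 0.1), 9 with DESeq2, 9 with the mouse as a replicate block, 8 with that block and length-corrected offsets, 12 with the set as a term, 12 in set A, 9 in set B, 0 with an estimated correlation and 0 with fry, and ranged from 5 to 11 without each library in turn. The block changed no other call. With log2(FPKM + 0.1) and log2(FPKM + 1) the MuSC medians were -1.74 and -1.25 for mature myofibre markers and 0.36 and 0.36 for ribosomal proteins, whose call was lost with log2(FPKM + 1) and with its scaled form (0.42), and cytokines were at 0.55 with log2(FPKM + 1). In set A, with 1 library after, the medians turned to -0.04 for glycolysis, -0.24 for ribosomal proteins and 0.38 for mature myofibre markers.

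In muscle, the count of 0 genes became 12 without a filter on low counts, which left more genes in the fit, 6 with DESeq2, 1 in the 2-sham table and 41 in the 1-sham table, and ranged from 0 to 4 without each library in turn. It stayed at 0 with no term for the table (626 at an unadjusted p under 0.05), a setting that ended the tenocyte (-0.26), Wnt (-0.17) and erythroid (-0.27) calls and gave 0.22 for ribosomal proteins. The count of 12 muscle lists became 3 without both transplanted 4 and sham 12, 0 with an estimated correlation and 0 with fry. Medians turned to -0.01 for ribosomal proteins and -0.02 for atrophy and autophagy with both log2(FPKM + 0.1) and log2(FPKM + 1), which gave 0.03 for glycolysis and 0.14 for oxidative phosphorylation and ended the Wnt (-0.21) and erythroid (-0.47 and -0.46) calls. The scaled log2(FPKM + 1) ended the ribosomal protein (0.08), Wnt (-0.13), atrophy (0.07) and erythroid (-0.38) calls. Without transplanted 4 and sham 12 the medians turned to -0.02 for ribosomal proteins, -0.06 for oxidative phosphorylation and 0.07 for fibroadipogenic markers. Oxidative phosphorylation was at -0.07 in the 2-sham table and ranged from -0.07 (without sham 12, which leaves the same contrast) to 0.41 (without sham 3) over single omissions, and immediate early genes from -0.42 (without sham 192) to 0.09 (without sham 3).

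Of 560 values of 29 named MuSC genes over the alternatives, 548 kept their side of the threshold and 12 crossed it, and of 885 values of 43 muscle genes 866 and 19 did. The sign turned in at least 1 alternative for 10 of these MuSC genes (Cdkn1a, E2f1, Fos, Mki67, Myod1, Myog, Pax7, Rpl32, Rplp1 and Vcam1) and 9 of the muscle genes (Col1a1, Fbxo32, Myh1, Myh2, Myh3, Myh4, Myh7, Pfkp and Sfrp1). E2f1 ranged from -0.16 to 1.24, Rpl32 in MuSCs from -0.25 to 1.54 and Rplp1 from -0.62 to 1.62, each lowest in set A. Of 110 values of the 5 MuSC lists, 77 kept sign and call, 30 lost the call and 3 turned, and of 276 values of the 12 muscle lists these were 189, 77 and 10. In simulated counts with the MuSC spread, 0% of changes of log2 1 and 2% of log2 2 were recovered, so a count of 0 genes there leaves such differences undetected. With the muscle spread 75% and 98% were recovered, but with 100 changed genes of each size, which eases the adjusted threshold. Where fewer genes change, fewer may be recovered. In the real muscle data Ddit4 (1.77 ± 0.29) and Egr1 (-2.33 ± 0.42) did not pass. The count of 0 genes in muscle thus does not exclude changes of this size.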

Other observations

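The genes and values in this part were chosen after they were seen, and none of the gene differences between all libraries of the groups passed edgeR's test as designed. In other fits, Igfbp4 passed with DESeq2, in set A and without both after 5 and after 11, Smoc2 with DESeq2, Fos without a filter on low counts, without sham 192 and in the 1-sham table, Rn18s-rs5 without transplanted 94 and in the 1-sham table, and Fasn, Acly and Elovl6 in the 1-sham table. In MuSCs, single libraries after transplantation stood apart in genes of other programmes. After 11 held interferon-stimulated genes at 96.7 CPM for Irf7 and 477 CPM for Bst2, against at most 1.01 and 8.04 CPM in the other MuSC libraries. After 5 held Col6a3 at 479 CPM and the matricellular gene Smoc2 at 241 CPM, against at most 20.6 and 30.1 CPM elsewhere. Igfbp4, which binds insulin-like growth factors, was at 465, 54.9 and 2.28 CPM in after 5, 6 and 11 and at most 1.81 CPM before. Tbx1, a transcription factor of head muscle progenitors, was at 3.39, 20.1 and 0.526 CPM after and at 39.6, 45.5 and 24.5 CPM before. Of other Hox genes, Hoxd8 was at 7.33, 0.745 and 4.67 CPM after and at most 0.552 CPM before, whereas Hoxa10 differed by 0.02 ± 0.27 and Hoxc10 by -0.19 ± 0.30. Hotair, an antisense transcript within the HoxC cluster, differed by 1.13 ± 0.66, with overlapping groups.

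In muscle, Fasn, the fatty acid synthase, stood at 326 CPM in sham 3, 540 CPM in sham 12 and 23.2 CPM in sham 192, against 26.0 to 115 CPM in the transplanted libraries. Acly stood at 90.7, 138 and 15.6 CPM in these shams and at 17.5 to 48.4 CPM in the transplanted libraries, and Elovl6 at 35.9, 39.7 and 1.38 CPM against 2.24 to 13.9 CPM. The immediate early gene Fos followed the same order, with 88.5, 103 and 13.2 CPM against 12.4 to 26.9 CPM. Transplanted 6 held Pdk4, a brake on glucose oxidation, at 2340 CPM and the mitochondrial carrier Ucp3 at 188 CPM, against 172 to 547 and 63.9 to 80.0 CPM in the other muscle libraries. Rn18s-rs5, which resembles ribosomal RNA, ranged from 342 CPM in transplanted 4 to 12400 CPM in sham 12, with 369 CPM in transplanted 14.

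The labels describe the mice as male. Xist, transcribed from the inactive X chromosome of females, was measured at 2.63 to 84.08 TPM in 14 of the 15 libraries and at 0.01 TPM in transplanted 4. The Y-linked genes Ddx3y, Uty and Eif2s3y were at no more than 0.10 TPM and Kdm5d at no more than 0.16 TPM in all 15 libraries, transplanted 4 included. These values go against the label of male for the 14 libraries with Xist. In transplanted 4, which held the lowest adipocyte mean in muscle, Xist and the Y-linked genes were all near 0, so its sex stays open.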
